A study of Chlamydomonas reinhardtii with 3 samples.

How the data were processed

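Genomic DNA of the green alga Chlamydomonas reinhardtii, strain CC125, was analysed by whole-genome bisulfite sequencing, which reads methylated cytosine as cytosine and converted, unmethylated cytosine as thymine. There were 3 libraries, 1 from wild type cells and 2 from cmd1 knockout (cmd1 KO) cells. CMD1 is the TET homolog that gives the series its title. Per the labels' protocols, cultures were kept at 25 °C in light of 20 μmol photons per square metre and second, and were then moved to minimal medium under 300 μE. Per the labels' protocols, DNA with about 2% unmethylated lambda DNA was sheared to about 300 bp, and about 500 ng was bisulfite converted. Conversion rates from the lambda DNA were not used here. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36 and BSMAP were used. The genome build, the annotation, any coverage minimum, the region assigned to each gene and the cytosine contexts are not given in the sources used here.

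The data are 1 table with 17527 gene entries. For each entry it holds, per the file headers, the authors' count of sites in wild type and in cmd1 KO. It also holds the deposited methylation level as a fraction, printed below as percent, a difference, a relative change, a fold and a p-value. Per the file headers the deposited counts are numbers of sites, not reads, although the cmd1 KO count behaves as a number of distinct levels in the checks described here, so the read depth behind each level is unknown and no interval for a level can be given. The deposited fraction is a mean with equal weight over the values listed for a gene. In both columns the level times the number of sites was a whole multiple of 0.001 in 100% of genes, within 1e-06 of a step. Levels are empty for 201 entries, all with under 5 sites in at least 1 column, and these entries were left out, which leaves 17326 genes. The deposited difference was the cmd1 KO level minus the wild type level. The deposited fold was the relative change plus 1, with an offset of 1e-12 in the denominator, so it has no meaning in the 33 genes with a wild type level of 0. The deposited p-value of the authors is unadjusted, and its test is not given in the sources used here.

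The 2 cmd1 KO libraries share 1 column, and whether it holds 1 library, a mean or pooled reads is not given in the sources used here. Each genotype therefore has 1 value per gene, with no spread between replicates. The limma fit and the agreement between the cmd1 KO libraries that were planned before the data were examined could not be run. The planned binomial and Fisher tests over genes were not run, because genes are not replicates. Genes were instead counted when the cmd1 KO level differed from the wild type level by at least 10 percentage points, the size fixed in advance. The p-values of the authors' deposited table were adjusted over the 17326 genes by the Benjamini-Hochberg method. They compare lists of sites in these libraries, not genotypes. Exact Clopper-Pearson 95% intervals of shares of genes cover counting error only. They take genes as independent, so they do not measure the precision of a difference between genotypes.

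The number of sites was unrelated to gene length (Spearman's rho across genes -0.02 in wild type and -0.04 in cmd1 KO). To learn how the levels were averaged, p was recomputed for the 33 genes with a wild type level of 0, where every wild type site is at 0. A two-sided rank-sum test with normal approximation, continuity correction and tie correction was used, with each possible number of cmd1 KO sites at 0. On simulated data this search read 200 of 200 genes as having 1 site at 0 and no ties when each distinct level was kept once. It read 0 of 200 so when every site was kept. The first outcome was largely fixed by the construction, so it checks the search only. The second rests on simulated lists mostly longer than the 5 to 19 cmd1 KO sites of the 33 genes. Short lists hold fewer equal levels, so it does not give how often the search would misread such genes. No other way of listing sites was simulated.

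Of the 17527 entries, 17525 matched the reference table of assembly Chlamydomonas_reinhardtii_v5.5, which gave 0 of them a symbol. Coordinates were not used. Names were given only to 7 genes whose locus identifiers had been fixed in advance from the published nomenclature. These are LHCSR1, LHCSR3.1, LHCSR3.2, PSBS1 and PSBS2 (the photoprotection list), CMD1 and VTC2. Lists fixed by symbol (antenna, photosystem, carbon concentration, flagella, DNA methyltransferase and histone genes) could not be matched and have no result. The rule for named genes took the 10 largest differences in each direction among genes that differed by at least 10 points, and the 7 fixed genes. Because the reference gave no names, 2 identifiers in each direction are printed and the others are summarised. The median difference of the photoprotection list was ranked among 10000 random lists of the same size, matched in 50 bins on the mean level of both columns, as planned, and on the wild type level, as an addition. In 100 simulated lists of 5 genes over the 17326 genes, a shift of 5 points put 100 lists above the central 95% of random lists, and 6 unshifted lists fell outside it. That shift was larger than the excess of the photoprotection list, whose median was 6.50 points against 4.73 points in random lists. The simulation therefore does not show how often an excess of that size is found. Alternatives were differences of 5 and 20 points, a minimum mean level of 5%, centring, means over genes or sites, a minimum of 20 sites, and other denominators for the cmd1 KO level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.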

Results

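Cytosine methylation was measured in Chlamydomonas reinhardtii cells exposed to high light, in 1 wild type library and 2 libraries of a cmd1 knockout. The series asks whether the cytosine methylation level changes when CMD1, an algal TET homolog, is lost. The levels of 17326 genes were compared, each deposited as a mean with a number of sites. The wild type levels rested on 1454118 listed sites, with a median of 82 per gene. The cmd1 KO levels rested on 516767, with a median of 26 per gene. Site numbers are those the authors' table lists, and the cmd1 KO number behaved as a number of distinct levels rather than of sites. The cmd1 KO libraries are given as 1 value per gene, so no difference has a replicate check, and each describes these libraries.

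Most genes carried little methylation in wild type, and their deposited level was higher in cmd1 KO. The median level was 1.05% in wild type (quartiles 0.82% and 1.37%) and 5.89% in cmd1 KO (quartiles 5.03% and 7.03%). The level was higher in cmd1 KO in 17165 genes and lower in 161. That is a share of 99.1% higher (exact 95% interval 98.9% to 99.2%, with genes taken as independent). The median difference was 4.73 percentage points, and the central 90% of genes lay between 2.87 and 8.82 points. The median ratio of the levels was 5.52 among genes with a wild type level above 0. With each column centred on their common median of 4.05%, 46.8% of genes were higher in cmd1 KO, but centring brings this share near an even split whatever the data, so it does not check the direction.

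The levels of the genotypes appear to have been averaged over unlike lists of sites. In each of the 33 genes whose wild type level was 0, all wild type sites, from 5 to 36 per gene, stood at 0. In all 33, p in the authors' deposited table equalled the rank-sum p obtained with exactly 1 cmd1 KO site at 0 and no equal levels among the others, within a relative gap of 5.15e-13. A single pair of equal levels would have moved p by a relative 0.0022 or more. Over all genes, 15822 wild type means lay below the least mean possible for distinct levels in steps of 0.001, against 0 cmd1 KO means. The wild type lists of those genes thus held repeated levels. For cmd1 KO this allows distinct levels beyond the 33 genes but does not show them. When the cmd1 KO levels of a gene were summed and divided by the wild type site number where that was larger, the median cmd1 KO level was 1.81% and 92.1% of genes were higher in cmd1 KO. With 1.52 and 2.02 times the wild type site number, 62.9% and 33.6% were higher. These divisions count missing cmd1 KO sites as 0, so they give lowest possible levels and lower the share by construction. Unless stated otherwise, the cmd1 KO levels and differences given here are the deposited means and share the limit of unlike lists. The deposited p-values share it too, since p in the 33 genes matched a comparison of such unlike lists. In genes with little methylation, such a comparison can give a small p without a change in methylation.

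By the authors' deposited table with Benjamini-Hochberg adjustment, 16904 genes were higher and 42 lower in cmd1 KO at an adjusted p under 0.05. The same numbers passed 0.05 without adjustment. As p appears to compare the unlike lists described above, passing this threshold does not separate a change in methylation from the averaging. Differences of at least 10 points were fewer, with 607 genes higher and 16 lower in cmd1 KO, and 594 and 14 of these passed the adjusted threshold. These counts depended on the denominator of the cmd1 KO level: 186 genes were higher and 21 lower with the wild type site number where larger, and 76 were higher and 46 lower with 1.52 times the wild type site number where that was larger. With 2.02 times that number, 35 were higher and 167 lower. The factors are the median and the 95th percentile of the site ratio in genes at 40% or more in wild type. Missing cmd1 KO sites count as 0 under these denominators, which can only lower the cmd1 KO level. The growing number of lower genes thus follows from the denominator and shows no loss of methylation. Among the genes that differed by at least 10 points, 97.4% were higher in cmd1 KO, and 82.5% after centring. Across genes, which are not independent replicates, the levels of the genotypes had a Pearson's r of 0.91 and a Spearman's rho of 0.43.

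**Figure D1:**
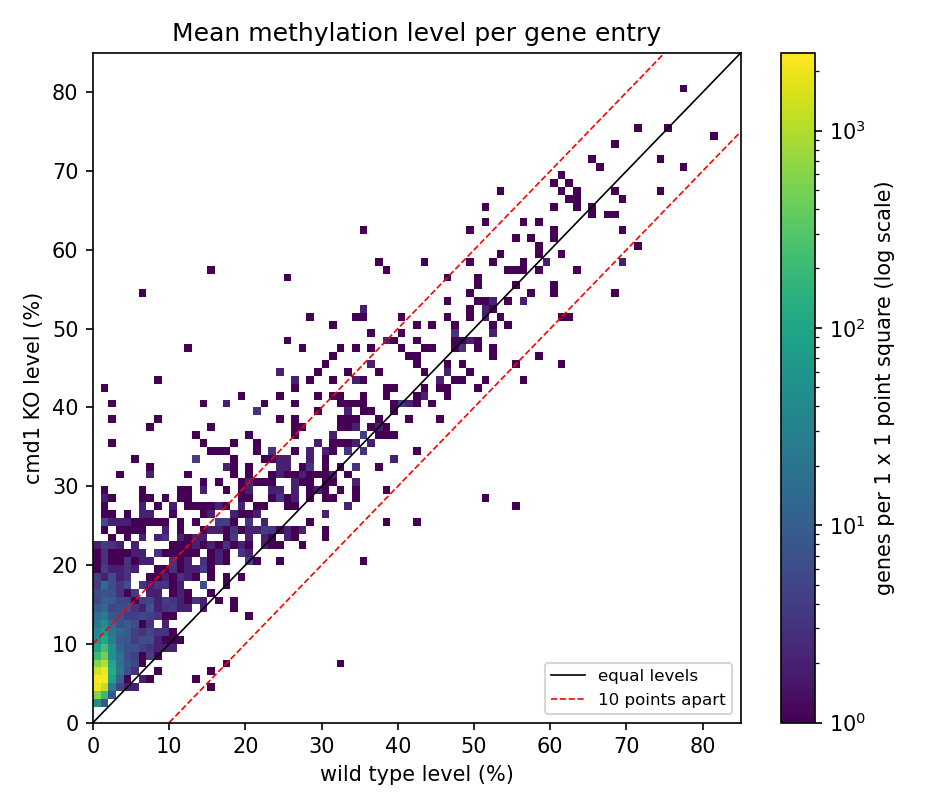
Mean methylation level per gene in wild type (x axis, %) against cmd1 KO (y axis, %), for 17326 genes, with colour giving the number of genes per square on a log scale. Most genes sit near 1.05% in wild type and 5.89% in cmd1 KO, and 607 genes lie on or above the upper dashed line against 16 on or below the lower one.

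The difference varied between classes of the wild type level, which also enters the difference itself. The 15697 genes under 2% in wild type, 90.6% of all genes, were all higher in cmd1 KO, with a median difference of 4.71 points. In the 198 genes between 10% and 20% in wild type, the median difference was 7.11 points and 184 genes were higher. In the 255 genes between 20% and 40%, it was 3.87 points and 196 were higher. The 150 genes at 40% or more had a median of 51.8% in wild type and 52.0% in cmd1 KO, with a median difference of -0.34 points, 70 genes higher and 80 lower. A level lower by 10 points is not possible in the 16723 genes under 10% in wild type, so the 16 such genes could lie only in the classes above. The ratio of cmd1 KO to wild type site numbers moved with the same classes, from a median of 0.30 in genes under 2% to 1.52 in genes at 40% or more.

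**Figure D2:**
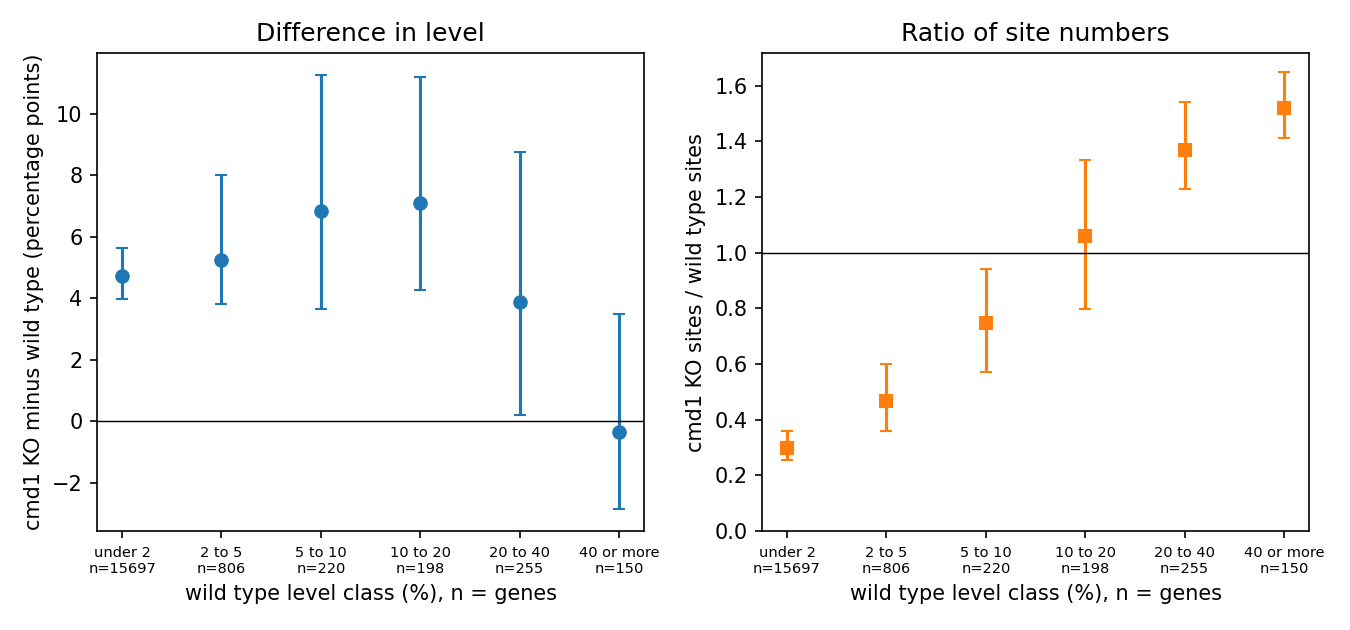
Median difference in level (left, cmd1 KO minus wild type, percentage points) and median ratio of site numbers (right, cmd1 KO over wild type) by class of wild type level (x axis, %), with bars from the first to the third quartile over genes. The difference is 4.71 points in the lowest class and -0.34 points in the highest, while the site ratio goes from 0.30 to 1.52.

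Among the genes with the largest differences, those higher in cmd1 KO had low to intermediate levels in wild type and intermediate levels in cmd1 KO. Cre02.g103770 stood at 6.99% over 90 sites in wild type and at 54.5% over 132 sites in cmd1 KO, 47.5 points higher (p = 4.05e-24 in the authors' deposited table, over sites). Cre25.g756197, on an unplaced scaffold, stood at 15.9% over 30 sites in wild type and 57.7% over 46 sites in cmd1 KO. The 10 largest differences towards cmd1 KO ranged from 30.1 to 47.5 points, from wild type levels of 1.44% to 25.8%. In the opposite direction, Cre15.g634582 stood at 55.2% over 16 sites in wild type and 27.1% over 76 sites in cmd1 KO, 28.2 points lower. Cre15.g634566 stood at 32.1% over only 5 sites in wild type and at 7.71% over 106 sites in cmd1 KO. The 10 largest differences towards wild type ranged from 11.9 to 28.2 points, from wild type levels of 32.1% to 68.1%.

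The photoprotection genes were all higher in cmd1 KO, and none of them by 10 points. LHCSR1, LHCSR3.1 and LHCSR3.2 encode stress-related light-harvesting proteins that act in the quenching of excess light energy, and PSBS1 and PSBS2 encode the photosystem II subunit S. LHCSR3.1 (Cre08.g367500) stood at 1.15% over 84 sites in wild type and at 9.01% over 32 sites in cmd1 KO, a difference of 7.86 points that exceeded that of 92.7% of genes. LHCSR3.2 (Cre08.g367400) stood at 1.30% and 6.69%, and LHCSR1 (Cre08.g365900) at 1.03% and 5.93%. Their differences of 5.39 and 4.90 points exceeded those of 68.1% and 55.5% of genes. PSBS2 (Cre01.g016750) stood at 1.00% and 8.46%, and PSBS1 (Cre01.g016600) at 1.93% and 8.44%. Their differences of 7.46 and 6.50 points exceeded those of 91.4% and 85.2% of genes. The LHCSR3.1 and LHCSR3.2 genes are near-identical copies, so reads shared between them make their separate values uncertain.

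The median difference of the 5 photoprotection genes, 6.50 points, lay at the 64.2nd percentile of random lists matched on the mean level of both columns. Matched on the wild type level, it lay at the 97.9th percentile, where random lists had a median of 4.73 points. The random lists drew genes independently, while LHCSR3.1 and LHCSR3.2, and also PSBS1 and PSBS2, have close locus numbers. If such genes vary together, both percentiles come from random lists that vary too little, and the 97.9th is overstated. The mean level contains the cmd1 KO level itself, so the first matching cannot show a difference of the list from other genes. Leaving out 1 gene at a time, the second percentile ranged from 91.8 without PSBS2 (92.0 without LHCSR3.1) to 98.8 without LHCSR3.2. All 5 genes passed the authors' deposited test after adjustment, the least of them PSBS1 with an adjusted p of 3.26e-05. The same was true of 16904 genes, and each of the 5 had 17 to 35 cmd1 KO sites against 57 to 84 wild type sites.

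CMD1 itself (Cre12.g553400) was among the least methylated genes. It stood at 0.43% over 99 sites in wild type and 3.32% over 24 sites in cmd1 KO, a difference of 2.89 points that exceeded that of only 5.18% of genes. A methylation level does not show whether the gene was disrupted, so it does not check the genotype labels. VTC2 (Cre13.g588150), the GDP-L-galactose phosphorylase of vitamin C synthesis, stood at 0.74% over 108 sites and 5.02% over 34 sites. Its difference of 4.29 points exceeded that of 36.2% of genes.

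**Figure D3:**
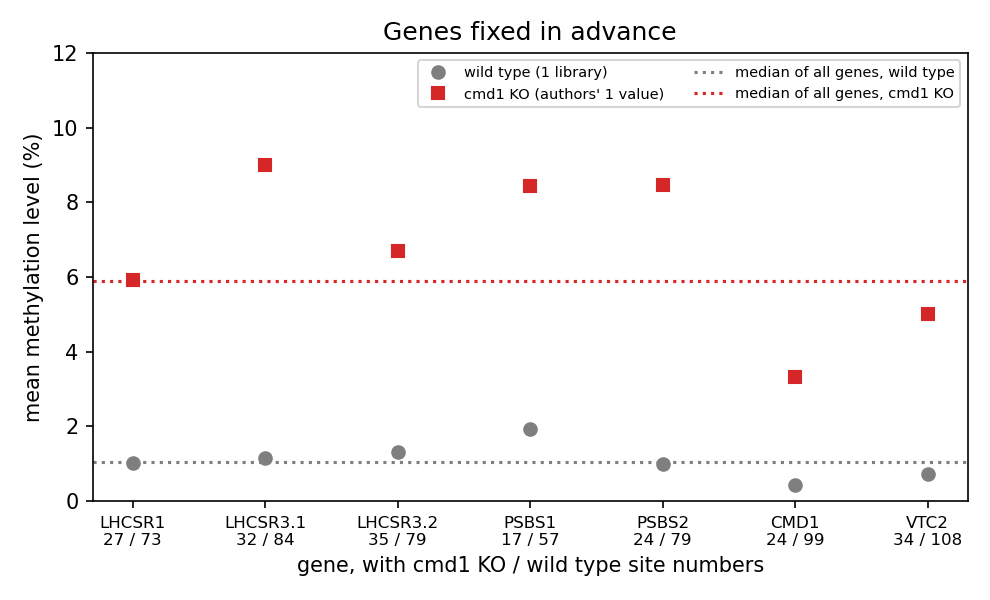
Mean methylation level (y axis, %) of the 7 genes fixed in advance, with circles for wild type and squares for cmd1 KO, site numbers under each name, and dotted lines at the medians of all genes. LHCSR3.1, PSBS1 and PSBS2 lie highest above the cmd1 KO median of 5.89%, and CMD1 lies lowest at 3.32%.

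The difference was spread over all chromosomes. The median difference per chromosome ranged from 4.62 points on chromosome 17 to 4.88 points on chromosome 8. The share of genes higher by at least 10 points ranged from 1.69% on chromosome 10 to 9.30% on chromosome 15 (exact 95% intervals 1.00% to 2.65% and 5.78% to 14.0%). Chromosome 15 also had the highest wild type median, 1.25%. The 242 genes on unplaced scaffolds were more often methylated in wild type, with 24.4% of them at 10% or more against 3.18% of the 17084 genes on chromosomes. Their median difference was 4.72 points. On scaffolds 19 genes, 7.85%, were higher by at least 10 points, and random lists matched on the wild type level held a median of 27 such genes (central 95% of lists 18 to 36).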

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

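The tests of the averaging, of the conversion and of the falls were chosen after the results they bear on had been seen. Although the cmd1 KO column had fewer sites over all genes, 600 genes had more sites in cmd1 KO than in wild type, which stood out because site numbers enter no comparison of levels. Of the 603 genes at 10% or more in wild type, 491 had more cmd1 KO sites, against 36 of the 15697 genes under 2%.

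Nearly all genes were higher in cmd1 KO. A technical explanation fits the tables: in 33 of 33 genes with a wild type level of 0, the deposited p is the one obtained with 1 cmd1 KO site at 0 and no other levels equal, as when each distinct level is counted once. Such averaging would collapse many zeros into 1 in unmethylated genes, and it may account for both the higher means and the lower site numbers there. What remains was bounded by assuming 1.52 times as many cmd1 KO as wild type sites, the median ratio in genes at 40% or more. The lowest possible cmd1 KO level then lay above wild type in 62.9% of genes and the highest possible lay below it in 0.421%. With 2.02 times as many sites, the 95th percentile of that ratio, these shares were 33.6% and 0.127%. The second share is small by construction at both ratios, so the pair of shares gives no direction. The highest possible level takes every missing site as fully methylated, while 16723 genes stood under 10% in wild type. Neither a genome-wide gain without CMD1 nor less complete bisulfite conversion can be told from no change, because the true site numbers and the conversion rates were not analysed here.

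Of the 607 genes higher by at least 10 points, the averaging leaves 35 that stay at least 10 points above wild type at their lowest possible level with 2.02 times as many cmd1 KO as wild type sites. In 7 of the 35 the cmd1 KO column already had that many sites, so the bound corrected nothing, and 28 remain for which it did. These 28 genes had a median of 7.24% in wild type and 36.5% in cmd1 KO, 2 of them on scaffolds. At that assumed ratio, Cre02.g103770 would stand at no less than 39.7% and Cre25.g756197 at no less than 43.9%. The ratio comes from listed cmd1 KO numbers, which behaved as numbers of distinct levels, so true site numbers could be larger. The levels could then be lower, and the averaging is not excluded for the 28 genes. A gain without CMD1 and a difference between cultures or libraries also stay open for them, since there was 1 wild type library.

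Of the 16 genes lower by at least 10 points, 13 stay below wild type at their highest possible level with the ratio of 1.52, and 8 with 2.02. The bound corrected nothing in 7 of the 13 and 3 of the 8, where the cmd1 KO column already had that many sites. The averaging may thus account for some of these values and is not excluded for the others, because the bounds rest on assumed site numbers. Few wild type sites are another open source, as 4 of the 16 genes had under 40. No biological explanation was tested.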

How the results depend on the processing

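Differences of at least 20 points were found in 70 genes higher and 3 lower (1.24% of scaffold genes higher), and of at least 5 points in 7226 and 44 (99.4% of them higher, 43.0% of scaffold genes higher). With a mean level of at least 5%, the medians were 2.64% and 12.01%, the median difference 8.05 points, 92.8% of genes were higher and Pearson's r across genes was 0.92. This rule keeps genes with little wild type methylation only where the cmd1 KO level is high, so selection raises the median difference. All 607 and 16 genes past 10 points were retained, which the rule ensures, since levels 10 points apart have a mean of at least 5%. Centring gave 46.8% of all genes higher and 82.5% of those past 10 points, and a median difference of -0.11 points. As means over genes the levels were 2.22% and 7.34% (difference 5.12 points), and weighted by sites 2.41% and 11.2% (8.81 points). Each column was weighted by its own site number, and the ratio of cmd1 KO to wild type sites rose with the wild type level. The weighted cmd1 KO mean thus leans more towards heavily methylated genes, and the 8.81 points compare unlike weights. The remaining alternatives, and the median difference after centring, were chosen after seeing the data. With at least 20 sites in both columns, 98.7% were higher, the photoprotection median (4 genes left) was 6.43 points and r was 0.93. With the summed cmd1 KO levels divided by the wild type site number where larger, 186 genes were higher by at least 10 points (89.9% of those past it, 4.55% of scaffold genes), 92.1% of all genes were higher, the cmd1 KO median was 1.81%, the median difference 0.74 points, the photoprotection median 1.57 points and r 0.95. With the site number expected at the ratio of 1.52, 76 genes were higher and 46 lower (62.3% of those past it and 62.9% of all genes higher, 3.31% of scaffold genes), the cmd1 KO median was 1.19%, the median difference 0.13 points, the photoprotection median 0.65 points and r 0.96. With the ratio of 2.02, 35 genes were higher and 167 lower (17.3% of those past it and 33.6% of all genes higher, 1.24% of scaffold genes), the cmd1 KO median was 0.90%, the median difference -0.16 points, the photoprotection median 0.17 points and r 0.95. These last differences shrink by construction, since missing sites count as 0. The median difference thus changed sign with the ratio of 2.02 and kept it under the other alternatives that give one, leaving aside centring, which sets it near 0 whatever the data. Coverage minimums, limma settings and leaving out a cmd1 KO library were not run, because the table gives neither coverage nor separate cmd1 KO libraries. No paired analysis was possible because the wild type has 1 library and the cmd1 KO libraries share 1 column. Read depth is unknown.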

Other observations

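Genes higher by at least 10 points in the deposited cmd1 KO level lay next to each other more often than random sets, but not under every denominator. Among the 607 such genes there were 83 neighbouring pairs, against a median of 40 (central 95% of draws 29 to 51, highest 62) in 10000 random sets matched on the wild type level, a test set before its result was seen. In tests added afterwards, the 186 genes left with the wild type site number as denominator had 19 pairs (central 95% of draws 6 to 18). The 76 genes left with the ratio of 1.52 had 2 pairs (0 to 6) and the 35 left with 2.02 had 0 (0 to 2). The hypothesis that neighbouring genes changed together thus stays undecided. The averaging of the cmd1 KO levels and windows shared between neighbours both remain open as technical sources. The same cmd1 KO site number and level was found in 3 of the 83 pairs and in 2 of the 19 pairs. As 19 pairs lay just above the upper end of 18, such identical entries could carry that excess.

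The photoprotection genes were set against the hypothesis that they only share the shift of all genes of like level. The limit written in advance was the upper end of the central 95% of random lists. The list passed it, at the 97.9th percentile, when matched on the wild type level, a matching added to the plan. In values added after seeing the data, with the summed cmd1 KO levels divided by the wild type site number or by 1.52 or 2.02 times that number, it lay at the 98.0th, 98.4th and 98.1st percentiles. The matching planned in the design, on the mean level of both columns, put the list at the 64.2nd percentile, under the limit. That matching decides nothing, since the mean level contains the cmd1 KO level. The shared shift was still left open, because the list passed the limit only narrowly and the random lists drew genes independently. The percentile was 91.8 without PSBS2, 92.0 without LHCSR3.1 and 97.3 without PSBS1. PSBS2 and LHCSR3.1 lie above the median of the 5 genes, so leaving out either must lower it. These drops therefore do not show that single genes carried the excess. The lowest possible level lay above wild type in 4 of the 5 genes at both ratios and below it in PSBS1, at 1.65% against 1.93% with the ratio of 1.52. LHCSR3.1 would stand at no less than 2.26% with 1.52 and 1.70% with 2.02, against 1.15% in wild type. LHCSR1 would stand at no less than 1.44% and 1.09%, against 1.03%. These lowest levels hold only if the genes had no more sites than the assumed ratios give.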
